A study of Homo sapiens with 6 samples.

How the data were processed

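Total RNA from LN229 cells was sequenced in 6 libraries, 3 labelled wild type (control) and 3 labelled TRIM25 knockdown; groups were taken from the genotype label and replicate numbers from the sample titles. Libraries were made with a stranded total RNA kit, per the labels' protocols. The submitters' processing notes name FastQC, MultiQC, Trim Galore and HISAT2 and the build hg19, without versions. The counting program, its strand setting and the gene annotation are not given in the sources used here.

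Each library had 1 deposited table of 28265 gene symbols with 3 columns. The authors' counts are whole numbers of reads per gene, neither normalised nor pooled, per the file headers and their values. The authors' FPKM column equals the count divided by a fixed gene length and by the column's own total count: the lengths this implies were whole numbers of bases (within 0.001) for all 21754 genes with a count. The authors' TPM column sums to 1000000 in each library and is the FPKM rescaled. Only the counts were tested, and the FPKM served to recover gene lengths, with a median of 2968 bp. No row lacked a gene name, and no column of another sample was present. Of the list of 13 mitochondrially encoded genes 0 were measured, so it is not analysed here.

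Total counts ranged from 11349865 to 16404725 per library. Every pair of libraries in a group differed by more than sampling noise (chi-square per degree of freedom between 1.95 and 8.54, over genes with at least 20 counts in the pair), so no library was a copy of another. The 10 most abundant genes took between 3.53% and 3.90% of counts.

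Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with the groups left 14315 genes holding 99.9% of counts, TMM factors ranged from 0.995 to 1.00, and glmQLFit and glmQLFTest were fitted with group as the only term over all 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The log2 fold change is labelled knockdown minus control; its standard error is its size divided by the square root of the F statistic, and the 95% interval uses the t distribution with the fit's total degrees of freedom. Unless stated otherwise, CPM values use TMM-scaled library sizes and are given as mean ± SD (n = 3).

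Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 23 lists with at least 5 measured genes, of 26 lists compiled from general knowledge. The lists, the tests, most other settings tried and the rule for named genes were fixed before the data were examined. The limit of 100 bp of shared exon, the comparison with matched random lists, the adjustment for length and GC and the families in the closing section were chosen after a first look at the fitted values. The rule for named genes took TRIM25, NONO, PRMT1, MYC, SFPQ, PSPC1 and NEAT1. It added the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes with a mean log2 CPM of at least 2 and groups that do not overlap, and up to 4 called members per list. UBD, KIAA0754, ITGB3, PCDHA1 and MBP were passed over in the 24 because they share at least 100 bp of exon, or a name, with another gene, and TRIM25 is already named; list members were named without this step. Of 82 called list members taken by the rule, 21 lost their call in at least 1 fit without a library. EWSR1, PRMT3, MMP9, SRSF4, RPS19, H1-2 and TRIM37 are given with those values. ASNS, EPSTI1, H2AC6, MKI67, POLE2, PRPF8, RPL31, RPS12, SALL2, SRSF9, SYP, TK1, TRIM35 and TRIM62 were left out of the examples after this was seen and are part of the counts only. The highest adjusted p that each of the 21 reached in these fits lay between 0.0532 and 0.208. DUSP1 and ZFP36, which kept their calls, were also left out of the examples. The values of 1 other gene taken by the rule are not reported here. On the library numbers, no label says that a number marks a shared day or batch, so no pairing was used. Samples with the same number did not deviate together from their group means.

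RefSeq symbols gave a biotype for 95.5% of the genes. GC content was the mean over a gene's transcripts in GENCODE v29 (95.3% of tested genes matched, but 0 of the 12 measured histone genes, for which the check is void); the reference is on another build than the files, so no coordinates are given. For each list, 10000 random lists were drawn in which each member was replaced by 1 of its 50 nearest genes in length, GC and mean expression. Members were drawn independently, so random lists do not carry the correlation between list genes, and percentiles among them are not p-values.

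The fit was tested on simulated data for this comparison: counts were drawn for the 14315 tested genes with the real means, library sizes and dispersions, and 200 genes were changed. The low-count filter, run again on the simulated counts, left 14192 genes. It called 82 of 100 genes changed 1.5-fold and 96 of 100 changed 2-fold in the right direction, and 13 of 13992 unchanged genes. Genes were simulated independently, without trends shared across the genes of a library. The simulation therefore does not show how many real calls stem from such trends. Alternatives were DESeq2 1.42.0, limma-voom, other normalisations and filters, a fold threshold, protein-coding genes only, the replicate number as a block, leaving out each library, other set tests and, added after seeing the data, a per-library adjustment for length and GC (loess).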

Results

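RNA sequencing of LN229, an established human glioblastoma cell line, gave 6 libraries in 2 groups of 3. The control group was labelled wild type, and the other group was labelled TRIM25 knockdown, made with a short hairpin RNA according to the series design. TRIM25 is an E3 ubiquitin ligase of the tripartite motif family. The sample titles of the control group carry the letters NC, which the labels do not explain, and do not say whether these cells were untreated or carried a non-targeting hairpin. Nor do the labels say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Total gene counts ranged from 13763400 to 15868470 in the control libraries and from 11349865 to 16404725 in the libraries labelled knockdown. After the low-count filter 14315 of 28265 genes were tested. The first principal component held 55.5% of the variance and separated the 2 groups.

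TRIM25 mRNA was higher, not lower, in the libraries labelled knockdown. It stood at 35.6 ± 0.243 CPM (counts scaled to library size; SD, n = 3) in the control libraries and at 82.9 ± 4.84 CPM (SD, n = 3) in the libraries labelled knockdown, a 2.34-fold difference. On the log2 scale this was 1.22 ± 0.07 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.23e-09). The raw counts were 561, 493 and 563 in the control libraries and 964, 905 and 1443 in the libraries labelled knockdown, so the groups did not overlap. Of the genes next to TRIM25 on the chromosome, COIL had a log2 fold change of -0.02 ± 0.07 (SE) and DGKE one of -0.66 ± 0.18 (SE). TRIM25 shares 132 bp of exon on the same strand with C17orf67, which had a log2 fold change of -0.16 ± 0.23 (SE), so some reads could be assigned to either gene. Because the targeted gene goes against the label, the groups are named by their labels throughout. All directions are given as labelled knockdown relative to control, and none of them can be read as the direction of an effect of losing TRIM25 mRNA.

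**Figure D1:**
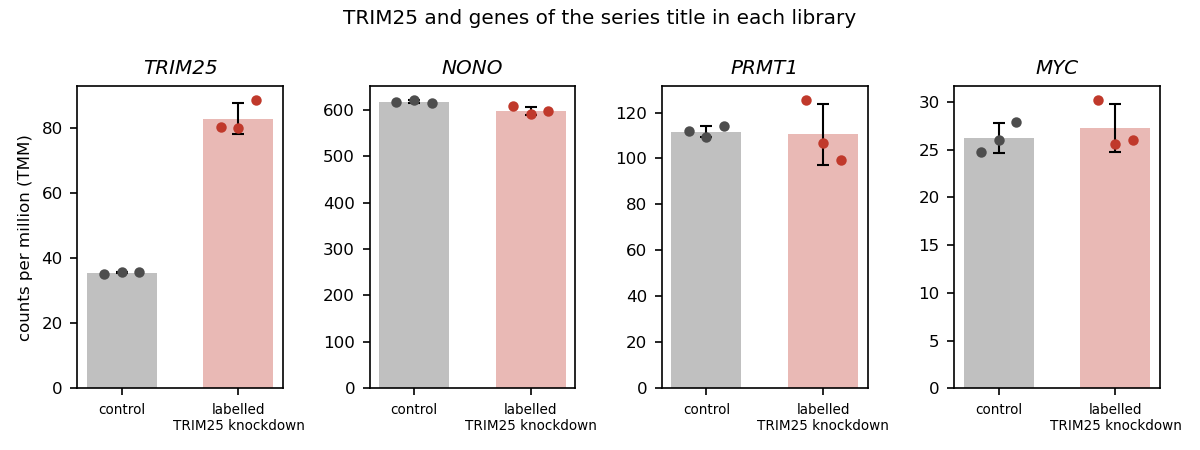
TRIM25, NONO, PRMT1 and MYC in each library, in TMM-normalised CPM on axes that start at 0. Points are libraries, bars are group means and error bars are SD (n = 3 per group). TRIM25 was 2.34-fold higher in the libraries labelled knockdown, and none of the other genes passed the test.

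The series title places NONO, PRMT1 and c-MYC downstream of TRIM25, so the mRNA of these genes was compared next. NONO, an RNA-binding protein of nuclear paraspeckles, stood at 617.0 ± 2.70 CPM in the control libraries and 597.9 ± 8.55 CPM in the libraries labelled knockdown (SD, n = 3 each). Its log2 fold change was -0.05, with a 95% interval from -0.15 to 0.06. PRMT1, the main asymmetric arginine methyltransferase, had a log2 fold change of -0.02 (95% interval -0.18 to 0.14) and shares 366 bp of exon on the same strand with ADM5, and the transcription factor gene MYC one of 0.05 (95% interval -0.13 to 0.24). The edgeR adjusted p values of NONO, PRMT1 and MYC were 0.532, 0.890 and 0.690. The NONO partners SFPQ and PSPC1 had log2 fold changes of 0.06 ± 0.05 and 0.10 ± 0.07 (SE). NEAT1, the long noncoding RNA scaffold of paraspeckles, had a log2 fold change of -0.12 ± 0.04 (SE) and missed the threshold (edgeR adjusted p = 0.0554), but passed it with limma-voom (adjusted p = 0.0470). After an adjustment for length and GC content, chosen after the data were seen, the NEAT1 log2 fold change was -0.32 (edgeR adjusted p = 1.44e-06). NEAT1 is 22741 bp long, against a median gene length of 2968 bp, so this value depends on how well the adjustment fits long transcripts. These are gene-level counts, so retained introns or other splice forms of PRMT1 were not measured.

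Most genes of the surrounding families did not pass the test. Of 20 measured paraspeckle genes and NONO partners, 1 rose and 1 fell. The one that rose was NUDT21, a cleavage factor subunit (log2 fold change 0.26 ± 0.06, SE), and the one that fell was EWSR1 (-0.16 ± 0.05). The EWSR1 call was lost without any of control replicates 1, 2 or 3 or of labelled knockdown replicates 2 or 3 (adjusted p from 0.0645 to 0.131). Adjusted over the list alone, 1 gene was higher and 0 were lower. Among 11 measured arginine methyltransferases and cofactors, PRMT3 rose by 0.31 ± 0.09 on the log2 scale. That call was lost without control replicate 1 (adjusted p = 0.103) or 3 (0.0816) and without labelled knockdown replicate 2 (0.130) or 3 (0.0716). Of 49 splicing factors 2 rose and 7 fell, and the kinase gene CLK1, which phosphorylates SR proteins, fell by 0.54 on the log2 scale. SRSF4 fell by 0.25, a call lost without control replicate 2 (adjusted p = 0.0540) or 3 (0.0585). Adjusted over the list alone, 1 splicing factor was higher and 6 were lower, and 1 methyltransferase gene was higher. None of these 3 lists stood apart from other genes as a set (limma camera, adjusted p = 0.914, 0.199 and 0.518).

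Across all genes, 3330 (23.3% of those tested) passed an edgeR adjusted p of 0.05, 1753 higher and 1577 lower in the libraries labelled knockdown. Most differences were small: the median size among these genes was 0.35 on the log2 scale. Of the changed genes, 41 were higher by at least 2-fold and 189 were lower by at least 2-fold. The number of calls changed when 1 library was left out. It was 3096, 1826 and 1877 without control replicates 1, 2 and 3 in turn. Without labelled knockdown replicates 2 and 3 it was 1868 and 2445. A fit with fewer libraries has less power, so these falls do not by themselves point to a particular library. The number was 4941 without labelled knockdown replicate 1, the library farthest from the others on the second principal component (-19.8). In 5342 of the tested genes (37.3%) the 2 groups did not overlap in CPM, where the average over all possible splits into 3 and 3 is 10%. Genes share trends across a library, so a single split can lie well above that average.

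LCN2, which encodes the siderophore-binding protein lipocalin 2, rose 6.19-fold from 9.58 ± 0.562 to 59.4 ± 5.35 CPM (SD, n = 3 each; log2 fold change 2.63 ± 0.09, SE; edgeR adjusted p = 7.51e-12). FDCSP, a secreted peptide gene, rose 2.80-fold, and NCR3LG1, which encodes a ligand of a natural killer cell receptor, 2.62-fold. The potassium channel gene KCNN3 rose 2.25-fold, the cytokine gene IL34 2.19-fold and the adaptor gene FYB1 2.09-fold. The interleukin 1 genes IL1A and IL1B rose 2.03-fold and 1.98-fold. BRCA2, a homologous recombination gene, rose 2.01-fold. The remaining 3 of the 12 genes named for the largest increases were RASAL1, NRIP1 and IGSF9B, with fold changes of 1.99, 1.97 and 1.95. NRIP1, a nuclear receptor corepressor gene, was the most abundant of these 12, at 108.9 ± 7.66 and 214.4 ± 27.8 CPM (SD, n = 3 each).

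SLC5A4, a solute carrier gene, fell 7.02-fold from 11.7 ± 1.48 to 1.64 ± 0.214 CPM (SD, n = 3 each; edgeR adjusted p = 6.50e-09). The matricellular gene POSTN fell 5.17-fold. COL5A2, which encodes a type V collagen chain, fell 5.09-fold from 51.4 ± 2.86 to 10.0 ± 1.39 CPM (SD, n = 3 each; log2 fold change -2.35 ± 0.10, SE; edgeR adjusted p = 5.27e-11). The ABC transporter genes ABCA8 and ABCG1 fell 3.85-fold and 3.48-fold; ABCG1 exports cholesterol. OLFML2B, TMEM100, OTULINL and IGFBP4 fell 3.65-fold, 3.59-fold, 3.39-fold and 3.34-fold. NNMT, which methylates nicotinamide, fell 3.13-fold, AGMO, an ether lipid monooxygenase gene, 3.09-fold, and COLEC12, a scavenger receptor gene, 3.06-fold. Apart from COL5A2 and OTULINL, these 12 genes had mean levels of at most 11.7 CPM in the control libraries.

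**Figure D2:**
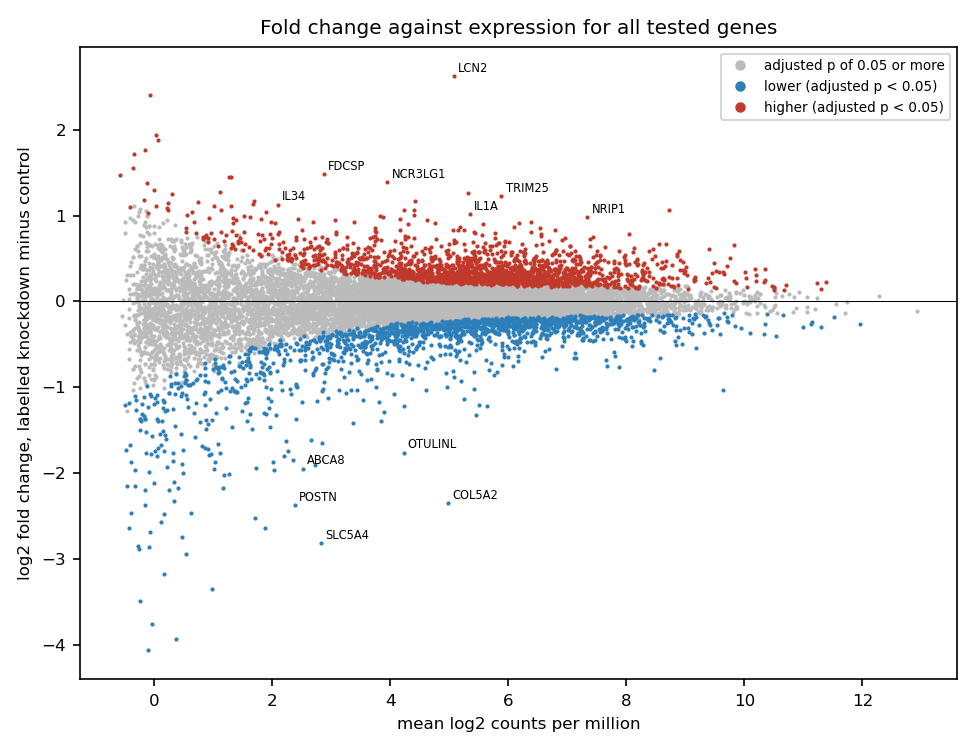
Log2 fold change (labelled knockdown minus control) of each of the 14315 tested genes against its mean log2 CPM. Red and blue points passed an edgeR adjusted p of 0.05; there are 1753 higher and 1577 lower genes, and TRIM25 lies among the higher ones at 1.22.

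Fold change also followed transcript length and GC content. Across 13640 genes with both values, Spearman's rho of the log2 fold change was 0.30 with length and -0.26 with GC; genes are not independent replicates. With genes in 5 bins of length, 97 were higher and 448 lower in the shortest bin (66 to 2002 bp), and in the longest bin (6382 to 93098 bp) 766 were higher and 183 lower. The trend also ran between libraries of 1 group. Relative to the group mean, rho with length was 0.43 in control replicate 1 and -0.38 in control replicate 3, and it was -0.40 in labelled knockdown replicate 1 and 0.39 in replicate 3. For each tested gene list except the histone genes, whose GC content was not matched, the median was set beside 10000 random lists matched on length, GC and expression.

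**Figure D3:**
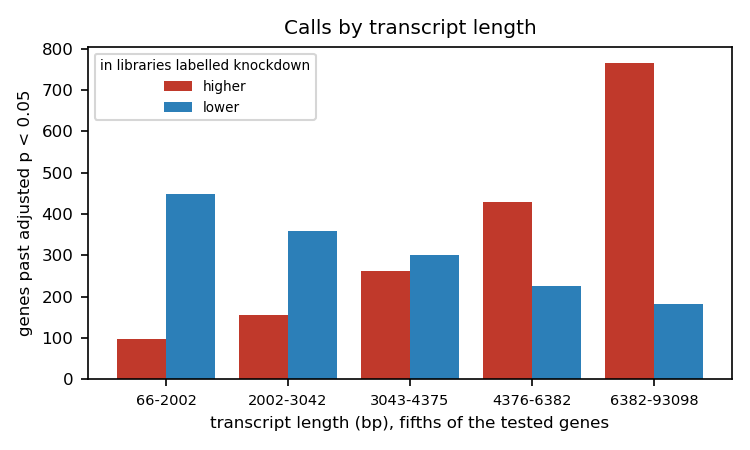
Number of genes past an edgeR adjusted p of 0.05 in each of 5 bins of transcript length, higher (red) or lower (blue) in the libraries labelled knockdown. Higher genes increased from 97 in the shortest bin to 766 in the longest, and lower genes decreased from 448 to 183.

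Of 36 measured glycolytic and hypoxia-responsive genes 22 fell in the libraries labelled knockdown, in which TRIM25 mRNA was higher, 3 rose and 11 did not pass; adjusted over the list alone, 28 fell and 3 rose. EGLN3, an oxygen-sensing prolyl hydroxylase gene, fell 2.23-fold. The lactate exporter gene SLC16A3 and the collagen prolyl hydroxylase gene P4HA2 fell by 0.61 and 0.59 on the log2 scale, from 167.4 ± 4.43 to 110.1 ± 9.34 CPM and from 264.9 ± 6.48 to 175.6 ± 3.34 CPM (SD, n = 3 each). The glycolytic enzyme gene GPI, whose exons overlap another annotated gene model, fell by 0.54 on the log2 scale. VEGFA, a hypoxia-induced angiogenic factor gene chosen after its value was seen, rose by 0.33. The list's median log2 fold change was -0.26 (camera adjusted p = 1.64e-08), below all of 10000 matched random lists, whose median was -0.02. With an estimated correlation the adjusted p was 0.200.

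Of 46 measured subunits of the mitochondrial respiratory chain encoded in the nucleus, 19 fell, 0 rose and 27 did not pass; adjusted over the list alone, 25 fell. NDUFA1 of complex I and COX7B of complex IV fell by 0.47 and 0.46 on the log2 scale, and NDUFA8 and COX7A2 each fell by 0.37. The median was -0.18 (camera adjusted p = 9.91e-07), against -0.08 for matched random lists, and lay below all 10000 of these. With an estimated correlation the adjusted p was 0.406. Cytosolic ribosomal protein genes, whose median length was 1142.5 bp, had a median of -0.08, and 8 of 76 fell while 0 rose; adjusted over the list alone, 6 fell. RPL39 fell by 0.32. RPS19 fell by 0.30, a call lost without control replicate 2 (adjusted p = 0.0821) or labelled knockdown replicate 2 (0.104). Their camera call (adjusted p = 0.0386) was lost with an estimated correlation (adjusted p = 0.836), and without control replicate 2 (0.204) or 3 (0.185) or labelled knockdown replicate 2 (0.117) or 3 (0.734). After length and GC adjustment the list's direction turned upwards (adjusted p = 0.0946), and matched random lists had a median of -0.11.

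Of 27 measured targets of NRF2, the oxidative stress transcription factor, 13 fell, 2 rose and 12 did not pass; adjusted over the list alone, 16 fell and 2 rose. The aldo-keto reductase genes AKR1C2 and AKR1C3, which share much of their sequence so that reads can be split between them, fell 1.66-fold and 1.63-fold, and the transporter gene ABCC2 fell 1.61-fold. HMOX1, the haem-degrading enzyme gene, rose 1.83-fold from 48.7 ± 3.81 to 89.2 ± 5.82 CPM (SD, n = 3 each). The list's median was -0.22 (camera adjusted p = 7.53e-05; adjusted p = 0.214 with an estimated correlation), against -0.03 for matched random lists.

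More interferon-stimulated genes fell than rose, and more NF-kB and cytokine genes rose than fell, in the libraries labelled knockdown, which had more TRIM25 mRNA. TRIM25 is known to act in antiviral signalling by ubiquitinating the RNA sensor RIG-I. Of 49 interferon-stimulated genes 16 fell, 2 rose and 31 did not pass; adjusted over the list alone, 17 fell and 4 rose. IFI27 fell 3.17-fold, the virion tether gene BST2 2.63-fold from 20.2 ± 2.63 to 7.68 ± 0.221 CPM, and IFITM1, whose exons overlap IFITM2 in the annotation, 2.44-fold. IFIH1, an RNA sensor gene other than that of RIG-I, rose by 0.30 on the log2 scale. The RIG-I gene DDX58 had a log2 fold change of 0.11 ± 0.09 (SE) and did not pass (edgeR adjusted p = 0.382). IFIH1 and DDX58 were chosen after their values were seen. The median was -0.16 (camera adjusted p = 0.00105; adjusted p = 0.214 with an estimated correlation), below all 10000 matched random lists. Of 25 NF-kB and cytokine genes 11 rose, 4 fell and 10 did not pass; adjusted over the list alone, 12 rose and 7 fell. Beside IL1A and IL1B, the signalling adaptor gene TRAF1 rose 1.88-fold and the adhesion receptor gene ICAM1 1.49-fold, from 223.0 ± 4.50 to 331.4 ± 14.5 CPM (SD, n = 3 each). TNFAIP2, BCL3, PTGS2 and NFKBIA fell, with log2 fold changes of -0.44, -0.41, -0.34 and -0.30. These 4 were named after their values were seen. The NF-kB and cytokine list had a median of 0.17, against -0.04 for matched random lists. It did not pass as a set (camera adjusted p = 0.0696), but did without labelled knockdown replicate 3 (adjusted p = 0.0450) and after the length and GC adjustment (0.0234); adjusted p = 0.332 with an estimated correlation.

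Of 58 measured genes activated by MYC, which itself did not pass, 15 rose in the libraries labelled knockdown, 2 fell and 41 did not pass; adjusted over the list alone, 15 rose and 4 fell. The ribosome biogenesis genes MYBBP1A, RRP12 and NIP7 rose by 0.38, 0.38 and 0.36 on the log2 scale, and the coactivator gene PPRC1 by 0.35. The median was 0.08 (camera adjusted p = 0.0126), against -0.05 for matched random lists. The call was lost with an estimated correlation (adjusted p = 0.332) and without control replicate 1 (adjusted p = 0.0657). In the unfolded protein and ATF4 list 13 of 40 rose, 2 fell and 25 did not pass; adjusted over the list alone, 16 rose and 4 fell. ALDH1L2 and the cystine transporter gene SLC7A11 rose by 0.67 and 0.59 on the log2 scale, and the lipoprotein receptor gene VLDLR by 0.57. Of the chaperone genes CANX and HSPA5, also chosen after their values were seen, CANX rose by 0.24 on the log2 scale and HSPA5 had a log2 fold change of -0.05 ± 0.05 (SE). The median was 0.08, against -0.03 for matched random lists. This list's camera call (adjusted p = 0.0373) was lost with an estimated correlation (adjusted p = 0.404) and without control replicate 1 (0.116) or 2 (0.0583) or labelled knockdown replicate 1 (0.0866).

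**Figure D4:**
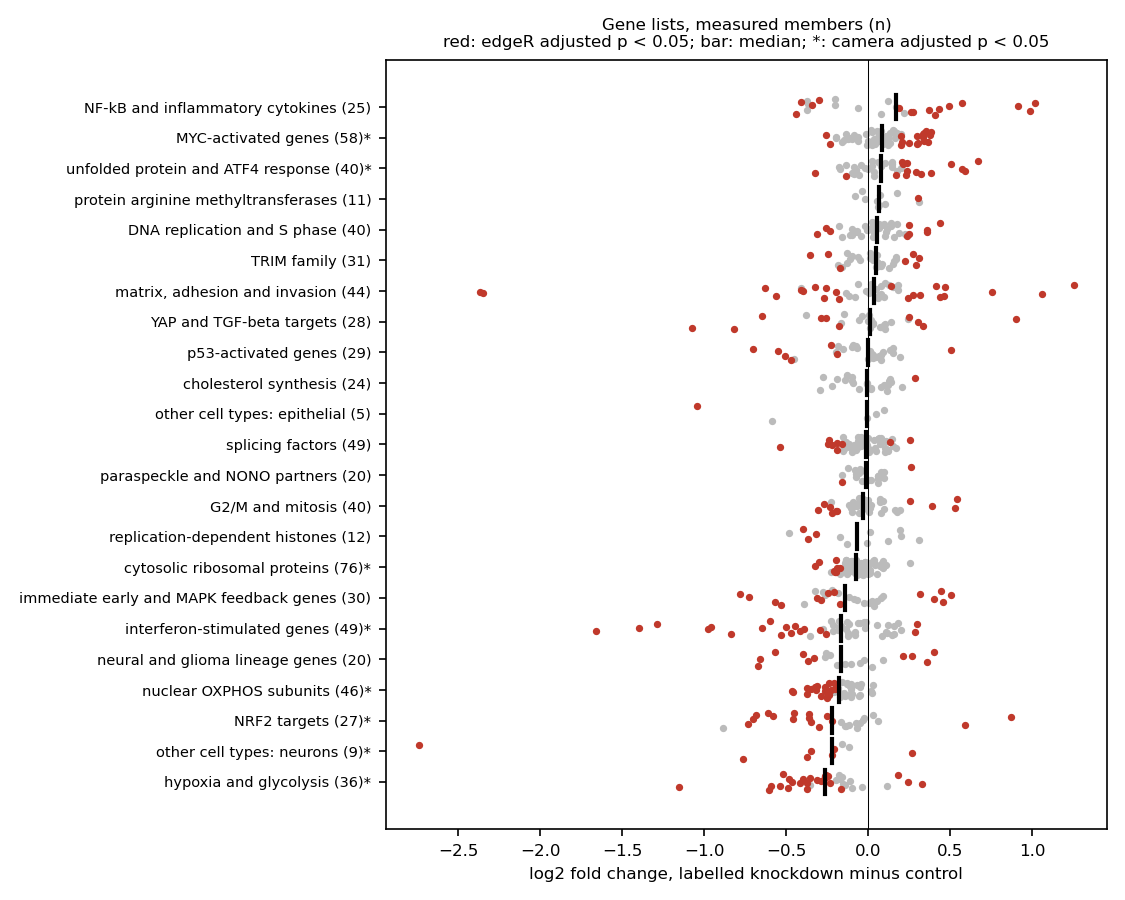
Log2 fold change (labelled knockdown minus control) of each measured member of the 23 tested gene lists. Red points passed an edgeR adjusted p of 0.05, black bars are list medians and asterisks mark 8 lists with a camera adjusted p under 0.05; medians run from -0.26 for hypoxia and glycolysis to 0.17 for NF-kB and cytokines.

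Of 40 mitotic genes 4 rose, 6 fell and 30 did not pass (median -0.03, mean 0.00084; camera adjusted p = 0.596). The long transcripts ASPM and CENPF, a spindle and a kinetochore gene, rose 1.45-fold and 1.44-fold, and BIRC5, which encodes survivin, fell 1.24-fold. Adjusted over the list alone, the counts were also 4 and 6. Of 40 DNA replication genes 6 rose and 3 fell, with DTL and POLE each rising 1.28-fold; adjusted over the list alone, 6 rose and 4 fell. The median was 0.05, against -0.02 for matched random lists. The list did not pass camera (adjusted p = 0.192), but did after the length and GC adjustment (adjusted p = 0.0185); adjusted p = 0.404 with an estimated correlation. Of 12 measured replication-dependent histone genes 3 fell, also adjusted over the list alone, and H2BC5 fell by 0.40 on the log2 scale. H1-2 fell by 0.32, a call lost without control replicate 2 (adjusted p = 0.0533) or 3 (0.108) or labelled knockdown replicate 2 (0.116) or 3 (0.0653). As a set the histone genes did not stand apart (camera adjusted p = 0.199). Histone genes are near-identical copies whose reads can be split, so their counts are uncertain.

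Matrix, adhesion and invasion genes went both ways, with 11 higher, 11 lower and 22 not passing of 44 measured; adjusted over the list alone, 14 rose and 13 fell. The median was 0.04 and the mean -0.04, and the list did not stand apart (camera adjusted p = 0.755). Beside POSTN and COL5A2, which fell, the integrin gene ITGB3 rose 2.09-fold from 274.9 ± 12.7 to 573.0 ± 36.8 CPM (SD, n = 3 each); its exons overlap another annotated gene model. MMP9, a gelatinase gene counted at 0.678 ± 0.368 CPM in the control libraries, rose 2.39-fold. The MMP9 call was lost without control replicate 1 (adjusted p = 0.0988) or 3 (0.0856) or labelled knockdown replicate 1 (0.0764). Among 28 YAP and TGF-beta targets 4 rose and 6 fell, also adjusted over the list alone. The BMP-responsive genes ID2, ID3 and ID1 fell 2.11-fold, 1.76-fold and 1.57-fold, and CCN1, a YAP target, rose 1.87-fold. The median was 0.01 and the mean -0.05 (camera adjusted p = 0.914). Of 30 immediate early and MAPK feedback genes 5 rose and 9 fell; adjusted over the list alone, 5 rose and 13 fell. The early growth response genes EGR1 and EGR2 fell 1.72-fold and 1.44-fold. EGR3, the AP-1 subunit gene FOSL1 and the feedback inhibitor gene SPRY2, chosen after their values were seen, rose 1.36-fold, 1.37-fold and 1.42-fold. The median of the immediate early list was -0.14, against -0.04 for matched random lists, and lay at percentile 0.42 of these. The list did not pass camera (adjusted p = 0.105), but did without labelled knockdown replicate 1 (0.0368). With an estimated correlation the camera adjusted p was 0.688.

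In the neural and glioma lineage list 4 of 20 measured genes rose and 6 fell; adjusted over the list alone, 4 rose and 7 fell. The stem cell transcription factor gene SOX2 fell 1.58-fold from 173.5 ± 3.85 to 109.9 ± 7.64 CPM (SD, n = 3 each) and OLIG2 fell 1.60-fold, while the receptor phosphatase gene PTPRZ1 rose 1.32-fold. The list's median was -0.17, against 0.00277 for matched random lists. It did not pass as a set (camera adjusted p = 0.0965), but did without control replicate 1 (adjusted p = 0.0388) or labelled knockdown replicate 2 (0.0319) or 3 (0.0110); adjusted p = 0.332 with an estimated correlation. Of 29 p53-activated genes 1 rose and 6 fell, also adjusted over the list alone; TP53I3 fell 1.63-fold, CYFIP2 1.46-fold and BTG2 1.42-fold, and FAS rose 1.42-fold (camera adjusted p = 0.340). Of 24 cholesterol synthesis genes 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.914). In a list of TRIM family genes compiled without TRIM25, 4 of 31 measured rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.780). TRIM33 rose 1.21-fold. TRIM37 rose 1.24-fold, a call lost without control replicate 2 (adjusted p = 0.0702) or labelled knockdown replicate 2 (0.0559).

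Of 18 blood and myeloid markers 3 were measured, and 2 of these rose: CD68 from 44.9 ± 1.09 to 63.3 ± 7.18 CPM and ITGAM from 1.22 ± 0.350 to 2.99 ± 0.514 CPM (SD, n = 3 each). Of 10 endothelial markers 3 were measured and 0 changed, and the most abundant, FLT1, had a log2 fold change of -0.11 ± 0.06 (SE). Of 14 epithelial markers 5 were measured and 1 fell, KRT14, at 3.19 ± 0.149 and 1.56 ± 0.310 CPM (camera adjusted p = 0.444). Of 9 measured neuronal markers 6 fell and 1 rose. NEFL, a neurofilament gene, fell 6.69-fold from 2.11 ± 0.897 CPM, SNAP25 fell 1.30-fold and GAD1 1.28-fold (camera adjusted p = 0.0126; adjusted p = 0.214 with an estimated correlation). The neuronal median was -0.22, against -0.01 for matched random lists. Counts adjusted over the list alone were the same for these 4 lists.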

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

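The adjustment for length and GC was chosen after the data were seen; all other alternatives were planned. TRIM25 stayed higher and past the threshold in each of 15 alternatives that gave its value, with log2 fold changes from 1.17 to 1.26, and the 24 genes named for the largest changes were all called in those 15. The count of changed genes fell from 3330 (1753 higher, 1577 lower) to 650 (298 higher, 352 lower) against a fold threshold of 1.2, where fewer genes can pass by construction. Leaving out 1 library gave between 1826 and 4941 changed genes, with 930 to 2622 higher and 866 to 2319 lower. Of the 6 NONO, PRMT1, MYC and partner genes, 1 (NEAT1) was called with limma-voom, with library totals, with upper-quartile factors and after the length and GC adjustment, where 0 were called in the main test; the cause was not tested. Of 8 lists called by camera, 0 were called with an estimated correlation, which has few residual degrees of freedom here. Directional fry tests each list against no change, not against other genes; it called 12, among them the DNA replication, p53, NF-kB, histone and lineage lists, but not the ribosomal proteins (adjusted p = 0.508). The ribosomal protein list turned from down to up after the length and GC adjustment (adjusted p = 0.0946), which also gave 4460 changed genes, 2795 of them shared with the main test. Among 115 named genes, 94 values over the alternatives lost and 6 gained a call, and 0 reversed. DESeq2 called 2572 genes. The share of higher calls ranged from 45.7% to 54.4% over the normalisations and filters. No label says that replicate numbers pair libraries, and the deviations of same-numbered libraries correlated at -0.19, 0.01 and -0.22. With the replicate number as a block, 1891 genes were called (967 higher, 924 lower) and the ribosomal protein list was not (camera adjusted p = 0.0872). By the deviations from the group mean, no library correlated best with its own number in the other group. By log2 CPM, control replicates 1, 2 and 3 each correlated best with labelled knockdown replicate 1 among the libraries labelled knockdown (0.989, 0.988 and 0.988). With the block and the length and GC adjustment together, 3868 were called. Depth limits the low genes: 1 CPM equals 11.3 to 16.4 counts, depending on the library.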

Other observations

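The tests of single mislabelled libraries, exchanged labels and collagen levels, and the gene families, were chosen after the results they bear on were seen, and the tests with matched random lists after the list medians were known. Grouping protein-coding genes by the start of their symbols gave 146 families of at least 10 measured genes, of which 8 passed camera (adjusted p under 0.05) and 0 did with an estimated correlation. In the libraries labelled knockdown, 5 of 10 UTP genes, which act in early ribosome assembly, rose and 0 fell (median log2 fold change 0.21). Of 456 ZNF genes, mostly zinc finger transcription factors, 67 rose and 14 fell (median 0.10), and 5 of 20 NUP nuclear pore genes rose while 0 fell (median 0.14). Of 12 NBPF genes 8 rose and 1 fell (median 0.47), but these are near-identical copies whose reads can be split. Set beside random families matched on length, GC and expression, the medians of the UTP, ZNF, NUP and NBPF genes lay at percentiles 99.7, 100, 98.2 and 100. CEP centrosome genes (12 of 35 rose) and USP deubiquitinase genes (10 of 46 rose) lay at percentiles 64.6 and 90.1, within what length and GC gave. Of the families that fell, 8 of 12 NDUFA and 8 of 20 COX genes fell and 0 rose, at percentiles 0.1 and 0.01; these overlap the respiratory chain list. Of 18 SEMA axon guidance genes 3 rose and 7 fell, and the family did not pass (adjusted p = 0.389).

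TRIM25 mRNA was 2.34-fold higher in the libraries labelled TRIM25 knockdown. A single mislabelled library is argued against, because the TRIM25 log2 fold change was at least 1.17 in each fit that left out 1 library. Reads from a neighbouring gene are argued against too: the higher of the log2 fold changes of DGKE and COIL, the nearest measured genes on either side, was -0.017. An exchange of the 2 groups' labels as a set stays open, since the lowest TRIM25 CPM in the libraries labelled knockdown was 2.24 times the highest in the control libraries and no other value in the tables fixes which cells carried the hairpin. Reads from a TRIM25 construct, or a true rise of the mRNA in cells with less protein, were not tested and may also be the cause.

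The hypoxia and glycolysis, respiratory chain, NRF2 and ribosomal protein lists were called lower in the libraries labelled knockdown by camera, and none was with an estimated correlation (adjusted p from 0.200 to 0.836), while fold changes followed transcript length and GC. Hypoxia and glycolysis, respiratory chain and NRF2 lists had medians of -0.26, -0.18 and -0.22, a larger fall than matched random lists (-0.02, -0.08 and -0.03). These 3 medians lay at percentile 0 of 10000 matched random lists. Random lists were drawn gene by gene, without the correlation between list members, so their spread is too narrow for co-regulated genes. The percentile therefore does not settle whether length and GC were the whole cause. After the length and GC adjustment, camera with the preset correlation still called these 3 lists lower. Their camera adjusted p values were then 2.78e-08, 0.000789 and 0.000730, in the same order. An estimated correlation was not tried on the adjusted values. The trend can account for the ribosomal protein list, at percentile 92.4, in which only 8 of 76 genes fell. The trend itself ran between libraries of 1 group, which is consistent with a difference in library preparation or RNA quality, but no label gives a batch. A biological difference between the 2 groups for the first 3 lists is a hypothesis found and examined on the same data, and stays untested.

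POSTN, COL5A2, DCN and COL15A1 were lower in the libraries labelled knockdown, with log2 fold changes of -2.37, -2.35, -1.17 and -1.15; DCN and COL15A1 were chosen after their values were seen. Fibroblasts mixed into the control libraries are argued against as the source of COL5A2, POSTN and COL15A1, since they would bring more type I and type III collagen. COL1A1, COL1A2 and COL3A1 together differed by 2.53 CPM between the groups (at most 3.54 between any control and any labelled knockdown library). The differences for COL5A2, POSTN and COL15A1 were 41.5, 6.54 and 8.58 CPM. CPM differences in this paragraph use library totals without TMM factors. DCN differed by 10.5 CPM (8.64 to 12.2 between any control and any labelled knockdown library), also more than COL1A1, COL1A2 and COL3A1 together. Its mRNA can rival collagen mRNA in fibroblasts, and how far it can exceed it was not examined, so fibroblasts stay open for DCN. Of 5 fibroblast genes only COL1A1 and LUM were measured, too few for their median log2 fold change (-0.30) to decide. COL1A1 fell by 0.56 from 5.33 CPM. LUM, at 44.6 CPM, had a log2 fold change of -0.04 ± 0.08 (SE, edgeR adjusted p = 0.712). Summed counts of COL1A2, COL3A1 and FBLN1, too few to test, were 27, 23 and 48 in the control libraries. They were 10, 5 and 17 in the libraries labelled knockdown. A shift within the LN229 population may also be the cause and was not tested.

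Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split, 1 of 10, called 3330 genes with edgeR (5144 at an unadjusted p under 0.05), and the highest other split called 0 (2090 at an unadjusted p under 0.05).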
